A study of Homo sapiens with 8 samples.

How the data were processed

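The study measured 5-hydroxymethylcytosine (5hmC), the first oxidation product that TET enzymes make from 5-methylcytosine, by hydroxymethylated DNA immunoprecipitation and sequencing (hMeDIP-seq) in HEK293T cells, an established human embryonic kidney line. Per the labels' protocols, cells were transfected with a plasmid that carried a GFP reporter and 1 of 4 constructs, sorted for GFP after 3 days (mTET1-CD and TET1-CD) or 7 days (mTET1-FL and TET1-FL), and their sonicated DNA was ligated to adapters, immunoprecipitated for 5hmC, size selected, amplified by PCR and sequenced as single reads. CD stands for the catalytic domain and FL for the full-length protein. The labels do not spell out the m prefix. In the published study it marks the catalytically inactive mutant, which served as the control, and this meaning is background that was not checked here. The 8 samples are an IP and an input sample for each construct. Samples were grouped by their titles, with 1 library per construct and fraction. The 4 input samples were not analysed here as files of their own, and enter only through the control tag column of the peak lists.

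Each of the 4 IP samples had 1 peak list, so peaks were called per library and not on pooled libraries. Per the file headers, each peak has a position, a number of IP tags, a number of control tags, a fold change and an FDR. The tag counts are whole numbers given for each peak and were used as deposited, with no normalization. Whether they count all tags of a peak is not given. The highest control count was 1100 in both full-length lists. The widest mTET1-CD peak spanned 87600 bp in a list with at most 249 IP tags per peak. The counts may therefore not be totals over the whole peak. The fold change is the authors' ratio of IP over control. It was a fixed function of the pair of tag counts in each list, with no pair carrying more than 1 fold, and was approximated as scale × IP tags / (control tags + constant). The fitted scale was 4.13 for mTET1-CD, 8.23 for TET1-CD, 5.88 for mTET1-FL and 5.83 for TET1-FL, and the fitted constant was 9.94, 12.2, 13.7 and 12.9 tags. The median error of the fit was 0.866% to 1.25% per list. The deposited FDR column was read as an adjusted p-value and lies between 0.001 and 0.049 over the 4 lists. The submitters' processing notes name hg18 as the genome build. The aligner and the peak caller are not given in the sources used here. Starts and ends were all multiples of 50 and the smallest start was 0, so starts were read as counted from 0, and positions are printed 1-based on hg18.

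The scale of the fold differs between lists, so that an identical pair of counts gives the highest fold in TET1-CD and the lowest in mTET1-CD. Folds were therefore used to describe, rank and filter peaks within a list, and 1 alternative, a fold minimum common to the 4 lists, inherits this difference. Another, the fold formula of mTET1-CD applied to the 4 lists, has the lowest scale and so by construction removes few mTET1-CD peaks. The sequencing depth of the libraries is unknown, since the lists give tags in peaks and no library totals. The IP tags summed over peaks were 1319955 in mTET1-CD, 4392745 in TET1-CD, 1584079 in mTET1-FL and 2055133 in TET1-FL, over covered lengths of 52.6, 396.6, 66.5 and 101.4 Mb. These sums move with how much was called and are not depths. They may also miss tags if the counts are not totals over each peak. The lowest IP tag count of a listed peak was 13 in mTET1-CD, 9 in TET1-CD and 12 in both full-length lists.

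For each list the peaks were counted, and covered length was computed after merging peaks that overlap. Peaks within 500 bp of each other were also joined to domains. Genome span was taken as the end of the last peak on each of 24 chromosomes over the 4 lists, 3077.87 Mb in all. Overlap was counted where peaks shared at least 1 base. It was set beside the mean of 100 circular shifts of the query list, each moving the peaks of a chromosome by 1 random distance within the chromosome, and beside 100 local shifts of 50 to 500 kb, which keep the regional density of peaks. Shares carry a Wilson 95% interval, and ratios of peak numbers per chromosome an exact binomial one. Both cover counting error only: tags were amplified by PCR without molecular identifiers, neighbouring peaks are not independent, and the difference between cultures is not included. With 1 library per construct no test between conditions was run and no p-value is given, so each difference is one between these libraries. The overlap procedure was tested on simulated data. Of 20000 simulated peaks, 10%, 40% or 70% were placed on TET1-FL peaks and the rest at random positions. Corrected for the share left by chromosome-wide shifts, the procedure recovered 9.82%, 39.3% and 69.6%. The overlaps reported below are raw shares without this correction, and real peaks cluster by region. The simulation therefore does not show that raw shares measure true sharing.

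The 4 comparisons, each form against its m form and the catalytic domain against the full-length protein within the active and the m constructs, were fixed before the data were examined, as were the alternatives of a fold minimum, joined peaks, equal list lengths, a larger required overlap, widened peaks, covered bases in place of peaks, and chromosome Y left out. Alternatives with a minimum of 13 or 20 IP tags, with the fold formula of mTET1-CD applied to the 4 lists, and without peaks of 100 or more control tags were added after seeing the data, as were equal list lengths for the shares of 1 Mb bins with most peaks, the settings for the number of X peaks, and 20 local shifts for each alternative overlap. The regions named were chosen by a rule fixed before the data were examined: the 5 peaks with the highest fold in each list, and the 5 bins of 1 Mb with the largest difference in share of peaks in each comparison. This rule stood in for one on genes. An annotation or sequence of hg18 was not used here, and the gene table at hand is of another build (GRCh38.p14), so peaks were not assigned to genes, promoters, exons or CpG islands. The 10 gene lists fixed beforehand (imprinted genes, HOX genes, developmental regulators, germline genes, tumour suppressors silenced by methylation, housekeeping genes, the DNA methylation machinery, CpG-poor tissue-specific promoters, olfactory receptors and clustered protocadherins) were not analysed here, and neither was the TET1 gene itself. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.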

Results

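Regions enriched for 5hmC were mapped by hMeDIP-seq in HEK293T cells sorted for GFP after transfection with the catalytic domain of TET1 (TET1-CD), the full-length protein (TET1-FL), or the m form of each (mTET1-CD, mTET1-FL). TET1 is a dioxygenase that oxidises 5-methylcytosine to 5hmC, and the full-length protein carries a DNA-binding CXXC domain that the isolated catalytic domain lacks. There was 1 IP library per construct. The lists held 61095 peaks for mTET1-CD, 314557 for TET1-CD, 75482 for mTET1-FL and 111648 for TET1-FL. The median peak held 20, 13, 19 and 17 IP tags, respectively, over 3, 3, 5 and 4 control tags. The catalytic domain samples were sorted on day 3 and the full-length samples on day 7, so that form and day cannot be told apart. No replicate check exists for any difference given here, and the Wilson and binomial intervals cover counting error only.

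The comparison of TET1-CD with mTET1-CD addresses where 5hmC-enriched sequence is found when the catalytic domain is overexpressed. TET1-CD had 5.15 times as many peaks as mTET1-CD, and they covered 396.6 Mb against 52.6 Mb, or 12.9% against 1.71% of the genome span. TET1-CD peaks were also wider, with a median of 1000 bp against 800 bp, and lay closer together, with a median gap of 2000 bp against 18950 bp. Joining peaks within 500 bp gave 10162 domains of at least 5 kb in TET1-CD, 4.06% of its domains (3.99 to 4.14%), and 50 in mTET1-CD, 0.085% of its domains (0.064 to 0.112%). The number ratio fell with a minimum of IP tags. It was 2.91 with at least 13 IP tags per peak and 0.778 with at least 20, where covered length remained 1.95 times larger. Depths are unknown, so the same minimum may be stricter in 1 list than in the other. The number ratio was 1.19 when the fold formula of mTET1-CD was applied to both lists, and 9.81 with the fold minimum common to the 4 lists. These fold settings lean opposite ways by construction, since the fold scale is lowest in mTET1-CD and highest in TET1-CD.

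Every autosome had more peaks in TET1-CD than in mTET1-CD, by 3.86 times on chromosome 1 to 6.57 times on chromosome 16 and by 5.28 times over all autosomes. Chromosome X had 5650 peaks against 2544, a ratio of 2.22 (2.12 to 2.33) that was 1.05 with at least 13 IP tags per peak, 0.155 with at least 20, 0.353 with a single fold formula and 4.13 with the common fold minimum. Its share of the whole list was 1.80% (1.75 to 1.84%) in TET1-CD and 4.16% (4.01 to 4.33%) in mTET1-CD. The difference in chromosome shares was 7.20%, the share of one list that would have to lie on other chromosomes for the lists to match. The 5 bins of 1 Mb with the largest difference all had a lower share in TET1-CD, although each had more TET1-CD peaks. Median control tags in each were 4 or 5 in both lists, while the median over all bins was 3 in mTET1-CD and 2.5 in TET1-CD. The reason for these higher control tags was not tested. The bin of chromosome 18 from 33000001 to 34000000 held 159 TET1-CD and 106 mTET1-CD peaks, and that of chromosome 1 from 30000001 to 31000000 held 201 and 114. The others lay on chromosome 1 from 110000001 (299 and 117 peaks), chromosome 7 from 150000001 (250 and 107) and chromosome 16 from 30000001 (244 and 104). The size of these differences changed with list length. In lists of equal length the share of TET1-CD over that of mTET1-CD was 1.24 in the chromosome 7 bin and 1.22 in the chromosome 16 bin, a reversal of both, and 0.957 in the chromosome 1 bin from 110000001 and 0.491 in the chromosome 18 bin, where the whole lists gave 0.496 and 0.291. In the chromosome 1 bin from 30000001 it was 0.447, against 0.342. The X share of TET1-CD was then 0.282 times that of mTET1-CD, against 0.431 times in the whole lists.

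**Figure D1:**
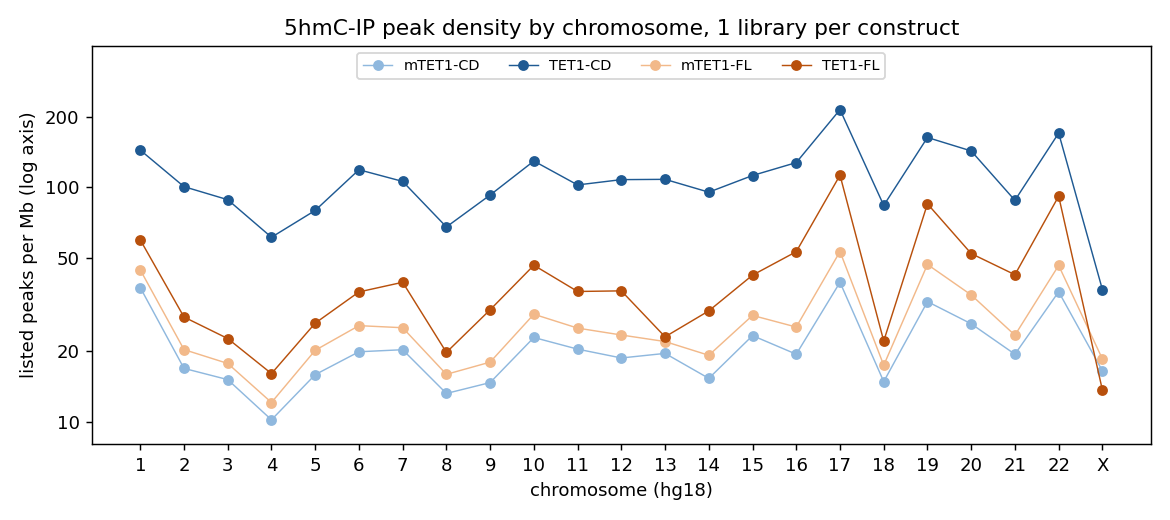
Listed peaks per Mb of genome span (log axis) on each autosome and X of hg18, with 1 point per library and chromosome and lines that only guide the eye. TET1-CD lies above the other lists on every chromosome shown, from 36.6 peaks per Mb on X to 214.0 on chromosome 17, and TET1-FL lies below both m lists on X at 13.6 peaks per Mb.

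Of the mTET1-CD peaks, 49.1% (48.7 to 49.5%) overlapped a TET1-CD peak, against 22.7% for chromosome-wide shifts and 34.4% for local shifts. In the other direction 9.52% (9.42 to 9.63%) of TET1-CD peaks overlapped an mTET1-CD peak, with 4.54% and 6.92% after shifting. The overlap was thus 1.43 and 1.38 times that left when the regional density of peaks was kept. The raw share was larger at the top of the mTET1-CD list: 72.6% of the 6109 mTET1-CD peaks with the highest fold overlapped TET1-CD, and 46.5% of the rest did. No shifts were run for these groups, so this difference has no reference. The 31109 mTET1-CD peaks without a TET1-CD peak show that the longer list did not contain the shorter one. In lists of equal length, 18.0% of TET1-CD and 19.6% of mTET1-CD peaks overlapped the other list, with 6.81% and 7.00% after chromosome-wide and 11.7% and 12.4% after local shifts.

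The 5 mTET1-CD peaks with the highest fold all overlapped a peak of each other list. They were led by a 2900 bp peak on chromosome 17 from 7018201 to 7021100 with 72 IP and 2 control tags, a fold of 24.8. The next was on chromosome 10 from 80755101 to 80757050, with 80 IP and 5 control tags and a fold of 21.95. The other peaks, on chromosome 19 from 11436151, chromosome 2 from 237166251 and chromosome 22 from 35320251, had folds of 20.9, 19.8 and 18.2. The top TET1-CD peak lay on chromosome 13 from 66627651 to 66629750, with 58 IP and 4 control tags and a fold of 29.4. It lies in a stretch of chromosome 13 from 61000001 to 68000000, singled out after its values were seen, where listed peaks had a median of 11 control tags in TET1-CD against 3 over the whole list. The following peaks were on chromosome 1 from 16922551 (5450 bp, fold 27.6), chromosome 2 from 3162551 (2550 bp, fold 26.8), chromosome 1 from 143239451 (6800 bp, fold 26.3) and chromosome 15 from 99895801 (8200 bp, fold 25.2). All 5 overlapped mTET1-CD and TET1-FL peaks, and 4 of the 5 an mTET1-FL peak, the exception being the one on chromosome 2.

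**Figure D2:**
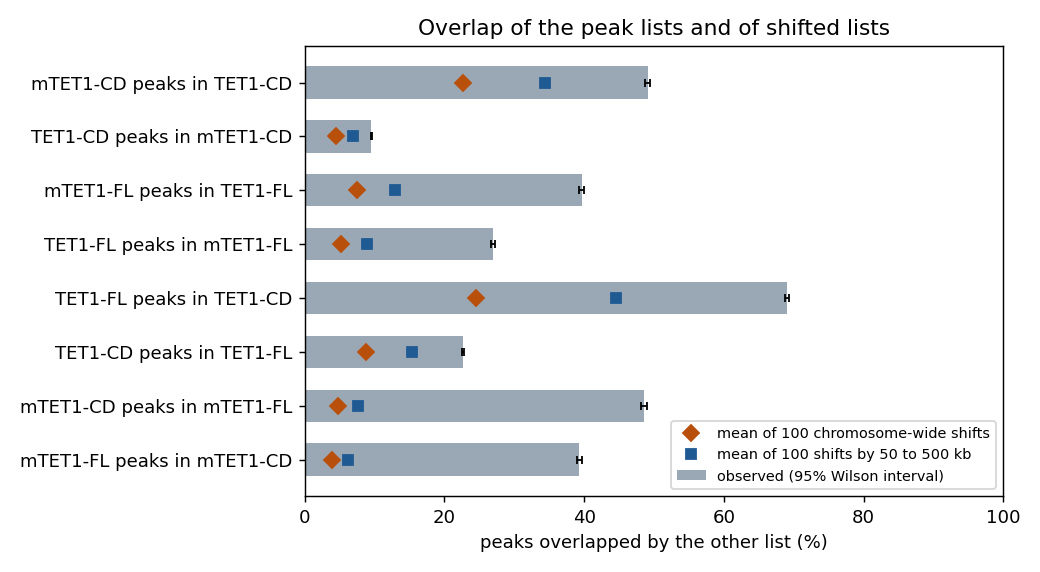
Share of peaks of the first-named list that overlap a peak of the second by at least 1 base (bars, with 95% Wilson intervals that cover counting error only), beside the mean share after 100 chromosome-wide shifts (diamonds) and 100 shifts by 50 to 500 kb (squares). Every bar extends past both markers, by the widest factor for the m lists, where 48.6% was observed against 4.76% and 7.59%. The factor is bounded by the inverse of the shifted share, so it has less room where the second list is TET1-CD.

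The same question was asked of the full-length protein. TET1-FL had 1.48 times as many peaks as mTET1-FL, covering 101.4 Mb against 66.5 Mb (3.30% and 2.16% of the span). Median widths were alike, 800 and 850 bp, and 322 domains of TET1-FL reached 5 kb (0.316% of its domains, 0.284 to 0.353%) against 59 of mTET1-FL (0.082%, 0.063 to 0.106%). With at least 20 IP tags per peak the order turned, with 33614 TET1-FL and 37637 mTET1-FL peaks, a ratio of 0.893, while the covered lengths were nearly equal at a ratio of 1.02. The number ratio was 1.12 with a single fold formula and 1.18 with the common fold minimum.

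The ratio of peak numbers differed between chromosomes. Chromosome 17 had 8838 peaks in TET1-FL and 4176 in mTET1-FL, a ratio of 2.12 (2.04 to 2.20), and chromosomes 16, 22, 19 and 21 had ratios of 2.10, 1.97, 1.81 and 1.81. Chromosome 13 had nearly equal numbers, 2622 against 2503, with a ratio of 1.05 (0.991 to 1.11). On chromosome X TET1-FL had fewer peaks, 2106 against 2857, a ratio of 0.737 (0.696 to 0.780) that was 0.383 with at least 20 IP tags per peak and 0.470 in lists of equal length, and the X share was 1.89% (1.81 to 1.97%) against 3.79% (3.65 to 3.92%). The chromosome shares differed by 7.44%. The 5 bins with the largest difference were all higher in TET1-FL and lay on chromosomes 16 and 17. They were chromosome 17 from 76000001 to 77000000 (334 peaks against 103), from 77000001 (261 against 74) and from 71000001 (247 against 64), and chromosome 16 from 1 to 1000000 (209 against 38) and from 87000001 (210 against 48).

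**Figure D3:**
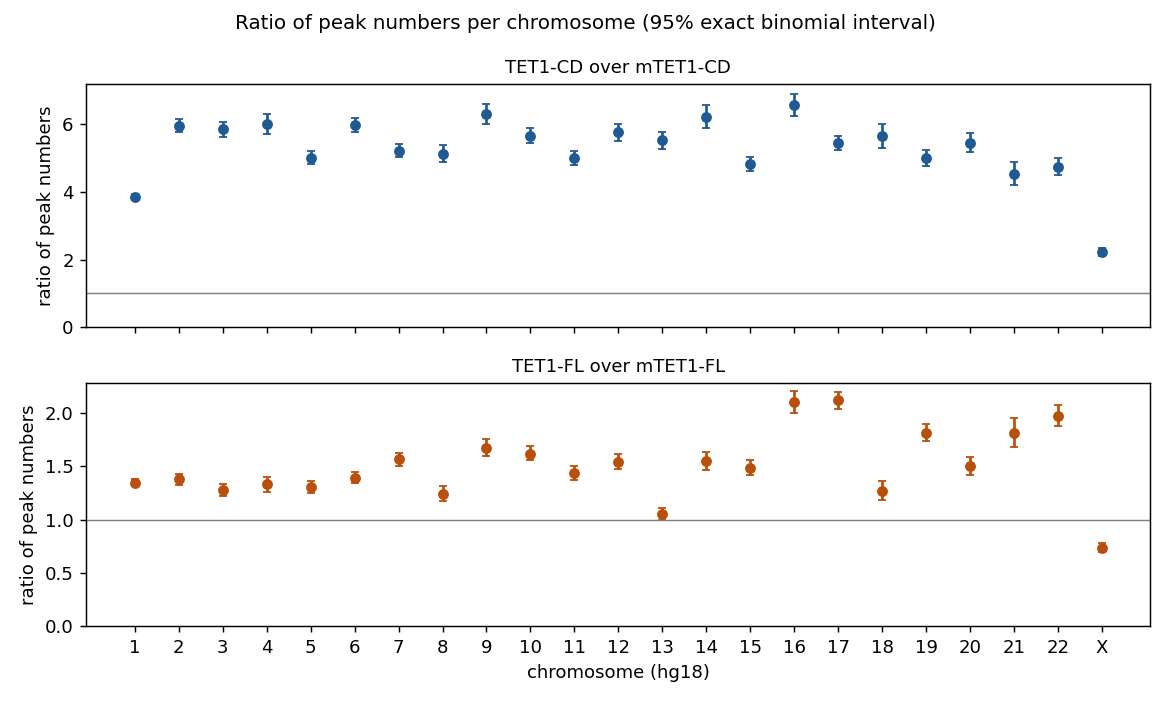
Ratio of the number of peaks on each autosome and X between an active form and its m form, TET1-CD over mTET1-CD (upper panel) and TET1-FL over mTET1-FL (lower panel), with 95% exact binomial intervals that cover counting error only and a grey line at 1. X has the lowest ratio in both panels, 2.22 and 0.737, and for TET1-FL its interval alone lies under 1.

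Of the mTET1-FL peaks, 39.7% (39.3 to 40.0%) overlapped TET1-FL, against 7.52% for chromosome-wide and 12.96% for local shifts. Of the TET1-FL peaks, 26.9% (26.7 to 27.2%) overlapped mTET1-FL, against 5.21% and 8.92%. The overlap was about 3.06 and 3.02 times the local expectation. Among the 11164 TET1-FL peaks with the highest fold 52.6% overlapped mTET1-FL, and 24.1% of the others did, with no shifts run for either group. All 5 top peaks of mTET1-FL were also in each other list. The first was on chromosome 18 from 4500251 to 4501400 (67 IP and 7 control tags, fold 19.6) and the second on chromosome 21 from 44202101 to 44204200 (83 and 11 tags, fold 19.5), followed by chromosome 7 from 155983051 and from 157925501 and chromosome 2 from 235087201 (folds 19.3, 18.3 and 18.1). The top TET1-FL peaks were on chromosome 16 from 84161801 to 84165100 (62 IP and 4 control tags, fold 21.1), chromosome 19 from 2054451 to 2056000 (49 and 1 tags, fold 20.4), chromosome 12 from 107523251, chromosome 4 from 1622951 and chromosome 1 from 181384751 (folds 19.1, 19.1 and 18.9). All 5 overlapped both m lists, and 4 of the 5 overlapped TET1-CD. The exception was the peak on chromosome 1.

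The catalytic domain and the full-length protein were compared to find what the part outside the catalytic domain adds to or removes from the pattern, with sort day differing in the same way. TET1-CD had 2.82 times as many peaks as TET1-FL and 3.91 times the covered length. With at least 20 IP tags the number ratio was 0.777, although covered length was still 1.63 times larger in TET1-CD. It was 1.65 with at least 13 IP tags, 1.38 with a single fold formula and 6.93 with the common fold minimum. Most TET1-FL peaks, 69.0% (68.7 to 69.3%), overlapped a TET1-CD peak, against 24.5% for chromosome-wide and 44.6% for local shifts. Of the 81574 TET1-FL peaks that had no mTET1-FL peak, 67.7% (67.4 to 68.01%) overlapped TET1-CD, against 23.9% for chromosome-wide and 43.8% for local shifts. Of the 30074 that had one, 72.6% (72.1 to 73.1%) did, against 26.01% and 46.7%. Conversely 22.7% (22.5 to 22.8%) of TET1-CD peaks overlapped TET1-FL, against 8.71% and 15.3%. This share was 52.3% among the 31455 TET1-CD peaks with the highest fold, for which no shifts were run. The share of TET1-CD peaks was 12.9% when at least 50% of the peak had to be covered and 10.1% with the common fold minimum. In lists of equal length 36.1% of TET1-FL peaks overlapped TET1-CD, against 8.84% and 20.5% for the shifts.

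At the scale of 1 Mb the active forms were close. Across 2865 bins the peak numbers of TET1-CD and TET1-FL had a Spearman rho of 0.95, against 0.80 for TET1-CD and mTET1-CD and 0.88 for TET1-FL and mTET1-FL. Bins are neighbours on a genome and not independent replicates. The 286 bins with most peaks held 39.7% (39.4 to 40.0%) of the TET1-FL list and 26.1% (25.9 to 26.2%) of the longer TET1-CD list, but 44.8% and 44.0% in lists of equal length, an alternative for this value added after seeing the data. The chromosome shares differed by 9.20%, and by 4.45% in lists of equal length. Among autosomes, chromosomes 22, 17 and 19 had the lowest ratios of TET1-CD to TET1-FL peaks, 1.86, 1.90 and 1.92, and chromosome 13 the highest, 4.70. As a ratio of shares, TET1-CD over TET1-FL was 0.660 on chromosome 22, 0.676 on chromosome 17 and 0.681 on chromosome 19 in the whole lists, and 0.989, 0.873 and 0.842 in lists of equal length, while chromosome 13 had 1.67 and 1.61. The X shares were 1.80% and 1.89% in the whole lists and 1.18% and 1.73% in lists of equal length. The 5 bins with the largest difference were all higher in TET1-FL by share. In 4 of the 5 TET1-FL also had more peaks in spite of its shorter list: chromosome 17 from 76000001 (334 against 230 peaks) and from 77000001 (261 against 192), chromosome 10 from 134000001 (318 against 241) and chromosome 16 from 30000001 (285 against 244). The fifth, on chromosome 22 from 36000001, held 306 TET1-FL and 316 TET1-CD peaks. TET1-CD peaks nonetheless held more bases in each of the 5 bins, from 1.64 times as many on chromosome 16 to 2.14 times on chromosome 22, and in the chromosome 17 bin from 76000001 they held 810.9 kb against 409.9 kb. In lists of equal length the TET1-CD share of these bins was 0.575 to 0.766 times the TET1-FL share, against 0.244 to 0.367 times in the whole lists.

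The m forms were compared as the background against which both active forms were set. mTET1-CD had 0.809 times as many peaks as mTET1-FL and 0.791 times the covered length (52.6 and 66.5 Mb). This order was reversed, at 1.30, when the fold formula of mTET1-CD was applied to both lists. That formula has the lowest scale, so by construction it kept nearly all mTET1-CD peaks (60965) and left 46877 mTET1-FL peaks. The overlap of the m lists exceeded the shifted values by a larger factor than in the other 3 comparisons, 10.2 times for chromosome-wide and 6.40 times for local shifts of mTET1-CD. Such a factor is bounded by the inverse of the shifted share, which rises with the covered length of the target list. Against the long TET1-CD list local shifts alone gave 34.4% for mTET1-CD and 44.6% for TET1-FL. The ranking against the comparisons with TET1-CD thus partly follows list size. Of the mTET1-CD peaks 48.6% (48.2 to 49.0%) overlapped mTET1-FL, against 4.76% for chromosome-wide and 7.59% for local shifts, and 39.3% (38.9 to 39.6%) of mTET1-FL peaks overlapped mTET1-CD, against 3.92% and 6.20%. Among the 6109 mTET1-CD peaks with the highest fold the share was 82.2%, with no shifts run for them. The chromosome shares differed by 2.14%, the least of the 4 comparisons, and the Spearman rho across bins was 0.95. Every autosome had fewer mTET1-CD peaks, from 0.694 times as many on chromosome 19 to 0.890 times on chromosome 13. The 5 bins with the largest difference were all lower in mTET1-CD. They lay on chromosome 19 from 1000001 (39 peaks against 83) and from 55000001 (61 against 110), chromosome 3 from 13000001 (55 against 99), chromosome 20 from 30000001 (29 against 66) and chromosome 17 from 7000001 (61 against 105).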

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

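Lists of equal length were fixed as an alternative for chromosome shares before the data were examined, and the other tests in this part were chosen after the results were seen. In the whole lists chromosome X had 2.22 times as many peaks in TET1-CD as in mTET1-CD, but 0.737 times as many in TET1-FL as in mTET1-FL, and was the one chromosome on which both intervals excluded 1 on opposite sides. The opposite directions depended on list length and tag minimum: the ratios were 1.05 (0.991 to 1.11) and 0.719 with at least 13 IP tags, 0.353 and 0.526 with a single fold formula, 0.155 and 0.383 with at least 20 IP tags and 0.282 and 0.470 in lists of equal length. With the common fold minimum they were 4.13 and 0.521. The difference between the forms itself was not tested, with 1 library each.

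Relative to the autosomes, the X share was lower in both active lists than in their m lists. List length alone does not account for it, since in lists of equal length the X share of TET1-CD was 0.282 times that of mTET1-CD and that of TET1-FL 0.470 times that of mTET1-FL. Equal length does not equalise the threshold: the lowest fold was then 8.80 in TET1-CD and 5.00 in mTET1-CD, and 5.64 in TET1-FL and 5.33 in mTET1-FL. The X share of TET1-CD itself fell from 1.80% in the whole list to 1.18%. An effect of the threshold thus stays open, at least for TET1-CD. At windows listed in both libraries, 272 on X for TET1-CD and 570 for TET1-FL, control tags did not fall as far as the X share. Relative to autosomes they were 0.953 times as high on X for TET1-CD (0.870 to 1.05) and 0.964 times for TET1-FL (0.922 to 1.005). These intervals come from 2000 resamples of the X windows with the autosomal value held fixed. They treat neighbouring windows as independent. IP tags there were 0.894 and 0.955 times as high. These windows were selected by being called in both lists and hardly show the X deficit itself, so they do not decide on fewer copies of X. X was also set against autosomal bins of 1 Mb with as many peaks in the m list of the other form. It reached 0.422 times their number for TET1-CD (0.362 to 0.484) and 0.471 times for TET1-FL (0.401 to 0.551), with intervals from resampled X bins. Matching on an m list mostly restates the lower X share relative to the m lists. Bins were not matched on sequence, so the values do not decide on the peak density of X. Lower 5hmC on X relative to autosomes under the active constructs stays open as a hypothesis, beside the threshold, the peak density of X and fewer copies of X. Testing it may need methylation data and replicate libraries.

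In a stretch of chromosome 10 near 70001551 the control column, which no comparison of the report took as its measurement, reached 1100 tags in mTET1-FL and 1100 in TET1-FL, and in TET1-CD, whose windows of this kind start at 70081201, it reached 639 at the window from 70115501, against list medians of 3 to 5. At the 19 listed windows with 100 or more control tags, IP tags were 0.794 to 0.993 times the control tags, and counts were close between libraries up to the same highest value, so enrichment there cannot be read from them. mTET1-CD listed 0 peaks in the interval, and neither full-length list had the TET1-CD window from 70081201 with 125 IP and 145 control tags, but these absences do not decide, since such counts give a fold of 3.33 by the formula of mTET1-CD and 4.63 and 4.61 by those of mTET1-FL and TET1-FL, below the lowest listed folds of 5.00. Extra copies in the genome of the cell line are argued against by TET1-CD, which had at most 8 control tags at windows where the full-length lists had 1083 to 1100, and a gain of the whole interval by the other 29 listed peaks there, whose median control tags were at most 3 in any list. Transfected plasmid DNA is a candidate source, although the windows were not matched to the TET1 gene, whose position on hg18 was not used here. Of the 7 windows in both full-length lists, 4 had 100 or more control tags in TET1-CD. The 2 with few were the first ones along the chromosome, which a shorter insert would lack. The other 1, from 70120051, was the last and was not listed in TET1-CD. In mTET1-FL and TET1-FL its IP tags were 0.951 and 0.912 times the control tags. TET1-CD listed a window at a lower ratio, 0.794 from 70102101, so a loss at 1 end only is not shown.

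The peak number of TET1-CD was 5.15 times that of mTET1-CD. With at least 13 IP tags in both lists, the tag minimum of mTET1-CD, the ratio was still 2.91, but with at least 20 it was 0.778. Depths are unknown, so these cuts do not decide whether the lower tag minimum of the TET1-CD list accounts for the excess. Library depth and fold scale cannot be told apart from a difference in 5hmC: with a single fold formula the ratio was 1.19, and the library totals were not used here. In lists of equal length TET1-CD covered 131.5 Mb with 4365 domains of at least 5 kb against 52.6 Mb and 50 domains. This sets the 61095 TET1-CD peaks with the highest fold against the whole mTET1-CD list. The kept TET1-CD peaks had a median width of 1700 bp, against 1000 bp in the whole TET1-CD list. The contrast thus partly reflects the selection and does not decide. An effect of the active construct remains open beside tag minimum, depth and fold scale.

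In TET1-CD, 6 peaks on chromosome 16 from 44943901 to 44985950 had up to 204 control tags and 108 to 220 IP tags.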

How the results depend on the processing

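The minimum of 20 or 13 IP tags, the single fold formula (that of mTET1-CD) and the omission of peaks with 100 or more control tags were added after seeing the data. Values are in the order TET1-CD to mTET1-CD, TET1-FL to mTET1-FL, TET1-CD to TET1-FL and mTET1-CD to mTET1-FL unless named, and causes were not tested beyond what is stated. The number ratio kept its direction in the 4 comparisons under the alternatives fixed before the data were examined. With the common fold minimum it was 9.81 for TET1-CD to mTET1-CD and 6.93 for TET1-CD to TET1-FL, a setting that the higher fold scale of TET1-CD favours by construction. With at least 13 IP tags these were 2.91 and 1.65, and with a single fold formula 1.19 and 1.38. With at least 20 IP tags the direction turned in 3 comparisons, to 0.778, 0.893 and 0.777, and with a single formula the m forms turned to 1.30. The single formula has the lowest fold scale, so by construction it favours the mTET1-CD list, of which it keeps nearly all peaks. Equal tag minimums may not be equally strict, as sequencing depths are unknown.

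The overlap of the first-named list stayed above its chromosome-wide and local shifts in every setting run. It was 4.60%, 22.9%, 12.9% and 46.2% when at least 50% of the peak had to be covered, 5.19%, 23.9%, 10.1% and 39.6% with the common fold minimum, 18.0%, 30.3%, 30.8% and 43.2% in lists of equal length, and 15.4%, 35.1%, 33.0% and 54.4% with peaks widened by 500 bp. The 24 overlaps in the second direction also stayed above theirs. Over both directions the overlap was 1.23 to 11.4 times the local value.

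The difference in chromosome shares was 10.4%, 8.68%, 4.45% and 2.44% in lists of equal length and 8.56%, 8.97%, 13.2% and 2.42% with the common fold minimum. By covered bases it was 8.35%, 7.47% and 2.28% for the last 3 comparisons, and with at least 13 IP tags 6.23% for TET1-CD to TET1-FL. Of 140 alternative values for share ratios of single chromosomes 10 crossed 1, in 7 of them from a main value whose list intervals lay apart. For TET1-CD over mTET1-CD these were chromosome 13 (0.970 at equal length, 0.967 by covered bases) and chromosome 22 (1.53 at equal length, 1.15 by covered bases, 1.15 with at least 13 IP tags), and for TET1-CD over TET1-FL chromosome 1 (1.01 with at least 13 IP tags) and chromosome 16 (1.03 at equal length). The other 3 were chromosome 19 in TET1-CD over mTET1-CD (1.23 at equal length, 1.07 by covered bases) and X in TET1-CD over TET1-FL (1.08 with the common fold minimum). Of 60 such values for the named bins 2 did, the bins of chromosomes 7 (1.24) and 16 (1.22) in TET1-CD over mTET1-CD at equal length.

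Leaving out chromosome Y or peaks with 100 or more control tags kept overlaps and chromosome differences, where run, within their counting intervals and number ratios within 1.5 times. Promoter windows of 2 kb and the alternatives for gene lists were not run, since genes were not assigned, and no library was left out, as there was 1 per construct. No paired analysis was possible because no result comes from a test. Library totals are unknown, so the peak numbers are not corrected for depth.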

Other observations

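Joining the 4 lists gave 383467 regions, of which 57.1% were found in TET1-CD alone, 10.5% in TET1-CD and TET1-FL together and 6.03% in TET1-FL alone. All 4 lists shared 13138 regions, 3.43%. The TET1-CD peaks that had no mTET1-CD peak overlapped TET1-FL in 18.8% of cases (18.7 to 18.9%), and those that had one in 59.5% (58.9 to 60.0%). Local shifts gave 14.5% and 23.6%.

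The outer 5 Mb at both ends of the chromosomes, 7.80% of the span, held 16.8% (16.6 to 17.04%) of TET1-FL peaks, 11.5% (11.2 to 11.7%) of mTET1-FL peaks, 12.1% (12.0 to 12.2%) of TET1-CD peaks and 10.4% (10.2 to 10.6%) of mTET1-CD peaks. Chromosome 1 held 15.1% of mTET1-CD, 14.5% of mTET1-FL, 13.2% of TET1-FL and 11.3% of TET1-CD peaks on 8.03% of the span, with median control tags of 5, 6, 5 and 4. On chromosome 13 from 61000001 to 68000000 median control tags were 13 in mTET1-CD, 11 in TET1-CD, 16 in mTET1-FL and 16 in TET1-FL, against 3, 3, 5 and 4 over the lists. This stretch held 0.624% of mTET1-CD peaks (0.564 to 0.689%), 0.537% of TET1-CD peaks (0.512 to 0.563%), 0.601% of mTET1-FL peaks (0.549 to 0.659%) and 0.278% of TET1-FL peaks (0.248 to 0.310%).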
